A study of Mus musculus with 2 samples.

How the data were processed

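Gene expression was measured with Affymetrix Mouse Genome 430 2.0 arrays, on which each transcript is probed by one or more sets of short oligonucleotides (probe sets), in osteoblastic cells from the tibia and femur of mouse embryos at embryonic day 18.5. The cells came from C57Bl/6 mice whose Ebf2 locus carries a lacZ marker. Per the labels, they were loaded with FDG, a substrate that becomes fluorescent when beta-galactosidase (the lacZ product) cleaves it, sorted by flow cytometry for the marker, and grown without passage in alpha MEM with 10% serum. Total RNA was prepared with Trizol and labelled with biotin by in vitro transcription. The heterozygous (Ebf2+/-) and the knockout (Ebf2-/-) group are represented by 1 array each. The labels give 3 mice for each genotype, and do not say whether their RNA was pooled on the array. Female- and male-specific transcripts were above background on both arrays, which points to RNA of more than 1 animal on each. Genotype was taken from the label of each sample, and no wild-type array was analysed here.

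The deposited values are the authors' MAS5 signals, a linear intensity for each of 45101 probe sets; MAS5 is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited intensity values ranged from 0.065 to 15980.0 on the heterozygote array and from 0.102 to 18361 on the knockout array. Leaving out the lowest and highest 2% of values, their mean was 99.96 on both arrays, so the authors' intensities had been scaled to one common target. Such scaling fixes the average signal of each array, and a shift shared by most genes would not be seen. MAS5 detection calls were not used here.

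Gene symbols came from the platform annotation. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed, among them most of the 64 control probe sets. The gene ID of 34754 probe sets was found in the mouse reference table (GRCm38.p6), and 0 symbols changed through it. Probe sets with several symbols or none stayed out of the gene comparison. The value of a gene was that of its probe set with the highest mean log2 signal over both arrays, which gave 18194 genes. For beta-actin and Gapdh this was the 3' control probe set. No genome coordinates are given, because the values carry none.

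Background was estimated from 86 probe sets for olfactory, vomeronasal and taste receptors, which bone cells are not known to use. Their 95th percentile, 17.8 on the heterozygote and 23.8 on the knockout array, was the floor. A gene was called measured when it was above the floor on at least 1 array (11785 genes), and lower values were set to the floor before the log2 ratio of knockout over heterozygote was taken. Where a gene was above the floor on 1 array only, its fold is a lower bound and is written "at least". No fold is given for the 609 measured genes whose signal on that array did not exceed the floor of the other.

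With 1 array per genotype there was no spread between animals or cultures to test against, so no p-value was computed and no gene is called significant. Genes are described by the size of the ratio, with 2-fold as the reference size. Error within the arrays was described in 2 ways. The log2 ratios of different probe sets of one gene had a pooled SD of 0.44 over 4119 genes, a factor of 1.36. The 18 probe sets for bacterial and phage spike-in transcripts had a log2 ratio of 0.18 ± 0.15 (SD over probe sets). Both leave out the variation between animals and cultures. The number of arrays limits the precision of every value.

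For 31 gene lists (504 genes, of which 465 had a probe set with 1 symbol), the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. The percentile describes these 2 arrays and is not a test across animals. Members without a fold enter a list's median at their floor-set value. Lists with fewer than 3 measured members received no percentile. Of the 29 lists that received one, 16 lay above the 97.5th and 4 below the 2.5th percentile. Lying outside the matched range was therefore common among these lists. The lists, the floor, the 2-fold size and the rule for the genes named in the text were fixed before the data were examined. The rule takes Ebf2; the 10 highest and 10 lowest ratios among genes above the floor on both arrays whose probe sets above the floor go the same way; the 5 brightest genes per direction that were above the floor on 1 array only, with no other probe set opposed by 2-fold or more; and, from each list, the 4 (lists tied to the study's question) or 3 (other lists) measured members with the largest ratio either way. The 112 genes it gives were all computed, and those that matter are printed. Other list members named in the text were chosen after their values were seen.

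The procedure was tested on simulated data built from the real mean signals with the noise between probe sets of one gene. Of the 12067 genes measured in the simulation, 128 unchanged genes came out at least 2-fold higher and 119 at least 2-fold lower. Of the genes simulated with a log2 change of 1.5, 78% were found at least 2-fold in the right direction, and 88%, 100% and 100% of those with a log2 change of 2, 3 and 4. Of 200 unchanged lists of 15 genes, 4% lay outside the 2.5th to 97.5th percentile. These lists were drawn at random with independent noise, so the share does not apply to lists of genes expressed together.

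Alternatives changed 1 choice at a time: the scaling (centring on the median, quantile, or lowess against mean signal), the floor (array median or 99th percentile of the receptor probe sets), no floor, genes above the floor on both arrays only, the mean over a gene's probe sets, leaving out probe sets ending in _s_at or _x_at, a pseudocount of 50, and sizes of 1.5-fold and 3-fold. Scaling to the spike-ins, leaving out leukocyte and chondrocyte genes and leaving out genes without a fold were added after the data were seen. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and matplotlib 3.10.9 for the figures.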

Results

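Expression profiles were obtained from lacZ-marked osteoblastic cells of heterozygous (Ebf2+/-) and Ebf2-deficient (Ebf2-/-) mouse embryos. Ebf2 is a transcription factor of the early B cell factor family, and the series title places the comparison in the support of haematopoietic stem cells by cells other than the stem cells themselves. There was 1 array for each genotype and no replicate, so every value below is a single measurement without a replicate check. Of 18194 genes on the arrays, 11785 were above background on at least 1 array and 10057 on both. The log2 signals of the latter correlated across genes with r = 0.94, which is a description over genes and not over replicates.

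In the knockout cells the secreted Wnt antagonists Sfrp1 and Sfrp2 were 21.2-fold and 23.1-fold higher than in the heterozygote, and the stem cell chemokine Cxcl12 was 4.56-fold higher. Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, was at least 5.11-fold lower. Macrophage and leukocyte genes were lower as a list (median log2 ratio -1.99), as were chondrocyte genes (-0.87), and adipocyte genes were higher (1.45). These differences describe 2 arrays. In all, 742 genes had at least 2-fold higher and 408 at least 2-fold lower signal in the knockout, 6.30% and 3.46% of the measured genes, and 10635 differed by less. At least 8-fold differences were seen for 22 genes that were higher and 6 that were lower. Noise between probe sets alone, which leaves out the variation between animals and cultures, gave 128 and 119 such 2-fold genes in simulated arrays. The balance between the directions depends on the scaling: with the arrays scaled to the spike-in transcripts, which lowers each log2 ratio by 0.18 and puts the median of genes above background on both arrays at -0.17, 528 genes were higher and 625 lower. Of the 271 genes past 2-fold that had several probe sets above background on both arrays, 227 had all of them in the same direction. The control 3' over 5' ratio, a sign of RNA integrity, was 1.97 in the heterozygote and 2.79 in the knockout for beta-actin, and 1.30 and 1.60 for Gapdh.

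**Figure D1:**
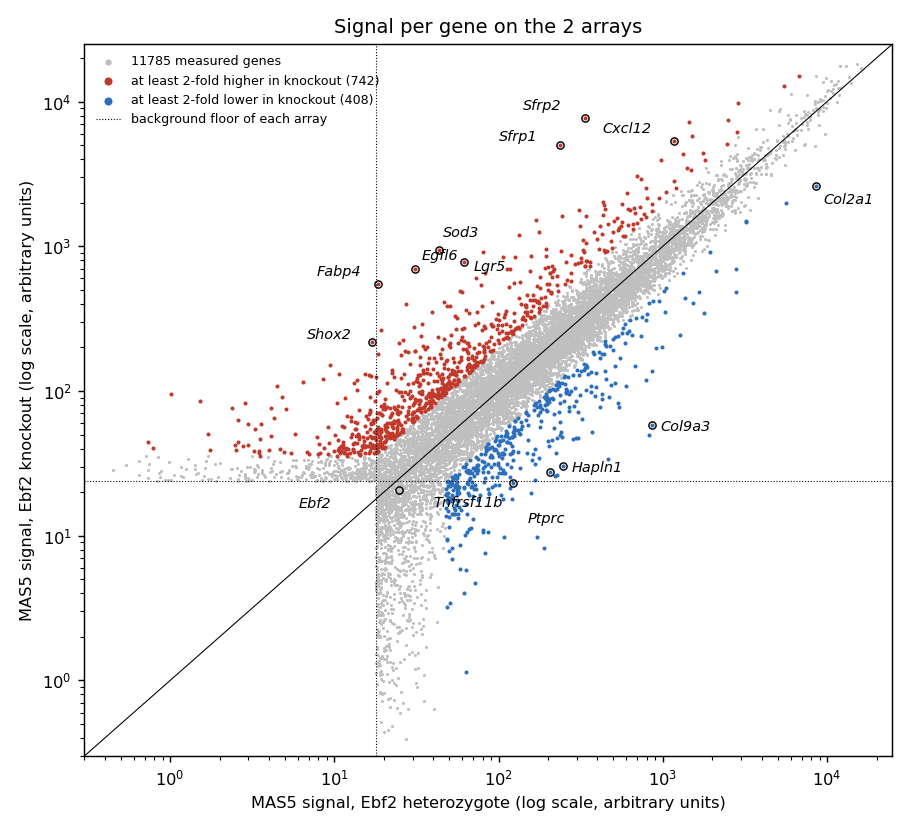
MAS5 signal of each of 11785 measured genes on the heterozygote array (x axis) and on the knockout array (y axis), both in arbitrary units on log scales; red and blue points are genes at least 2-fold higher or lower in the knockout with values under the floor set to the floor, dotted lines are the background floors, the line marks equal signal, and some genes named in the text are circled. Sfrp1 and Sfrp2 lie far above the line at knockout signals of 5029 and 7740.0, and Col9a3 lies far below it at 58.0.

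The Ebf2 transcript itself was near background on both arrays. Its brightest probe set read 24.9 on the heterozygote array (floor 17.8) and 20.6 on the knockout array, which is under the floor of 23.8. Another probe set read 14.4 and 25.1, above the floor in the knockout only, and the last read 13.7 and 14.4, below the floor on both. These signals do not separate the genotypes, and where the probe sets lie relative to the lacZ insertion is not known here, so they neither check nor contradict the labels. Among relatives and partners of Ebf2, Ebf3 was 4.52-fold higher in the knockout (116 against 523) and Ebf1 was 2.51-fold higher (199.6 against 500.3). All 3 probe sets of Ebf3 and the 4 probe sets of Ebf1 above background were higher, by at least 2.55-fold and 2.51-fold. Zfp423, which encodes a zinc finger protein that binds EBF proteins, was 2.27-fold higher (log2 ratio 0.62 with a pseudocount of 50), and its relative Zfp521 had 374 and 594. Of 7 measured genes of this list 3 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.67 (percentile 98.6 of matched random lists), and 1.18 over the 5 members above background on both arrays.

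Fabp4, a fatty acid binding protein of adipocytes, had the highest ratio and was 30.0-fold higher in the knockout (18.4 against 552), although its heterozygote signal stood only just above the floor; another of its probe sets gave at least 4.56-fold. The Wnt-binding antagonists Sfrp2 and Sfrp1 were 23.1-fold and 21.2-fold higher, Egfl6, a secreted protein with EGF repeats, 22.8-fold, and the extracellular superoxide dismutase Sod3 21.7-fold. Rasl11b (14.7-fold), the amine oxidase Aoc3 (13.7-fold), the R-spondin receptor Lgr5 (12.7-fold), the preadipocyte factor Dlk1 (11.3-fold) and Wfdc18 (9.75-fold) completed the 10 highest. The heterozygote signals of Aoc3 (19.2) and Wfdc18 (18.4) also stood only just above the floor. With a pseudocount of 50 their log2 ratios were 2.18 and 1.74. Of genes seen only on the knockout array, the homeobox gene Shox2 was at least 12.1-fold higher, Scg2 at least 8.44-fold, Pi15 at least 7.36-fold, Fmo1 at least 7.33-fold and Iigp1 at least 7.22-fold. The second probe set of Sod3 gave 6.90-fold, so the size of that ratio differs between probe sets. As a mean over probe sets the log2 ratio was 3.57 for Fabp4 and 2.24 for Iigp1.

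Among the lowest ratios were cartilage and leukocyte genes. Elobl was 16.6-fold lower in the knockout (820.3 against 49.4), the cartilage collagen Col9a3 14.8-fold (856 against 58.0), Crct1 13.8-fold, and the cartilage link protein Hapln1 8.19-fold, with 1.93-fold for its other probe set. The leukocyte integrin chain Itgb2 was 8.56-fold lower, Rgs1 8.47-fold, the pan-leukocyte antigen Ptprc (CD45) 7.45-fold and the macrophage scavenger receptor Msr1 6.89-fold, with 2.54-fold for its other probe set. The knockout signals of Itgb2, Rgs1, Ptprc and Msr1 (26.4, 25.9, 27.5 and 24.1) stood only just above the floor of 23.8. With a pseudocount of 50 their log2 ratios were -1.85, -1.83, -1.72 and -1.54. The neurotrophin receptor Ngfr was 7.14-fold lower and Moxd1 7.04-fold. Of genes seen only on the heterozygote array, the prostaglandin-degrading enzyme Hpgd was at least 7.96-fold lower, Fermt3, an integrin activator of blood cells, at least 7.15-fold, Cd84 at least 6.63-fold and the receptor Erbb3 at least 5.04-fold. The value of Fermt3 rests on a single probe set ending in _s_at; its log2 ratio was -1.57 without such probe sets and -1.25 as a mean over probe sets. For Ngfr that mean was -1.98.

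Tnfrsf11b, the gene of osteoprotegerin, the decoy receptor that restrains osteoclast formation, was among these genes seen only in the heterozygote. Its signal was 122 in the heterozygote and under the floor in the knockout, at least 5.11-fold lower, and the other probe set gave at least 4.29-fold. With a pseudocount of 50 the log2 ratio of Tnfrsf11b was -1.23. Of the 10 measured osteoblast factors that act on osteoclasts, 3 were at least 2-fold higher and 3 at least 2-fold lower. Il6 was at least 7.14-fold higher and the chemokine Ccl7 5.92-fold higher, while the chemokine Ccl9 was 2.61-fold lower. The median log2 ratio of -0.15 lay within matched random lists (percentile 21.2), and the mean, 0.09, had the opposite sign.

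Secreted Wnt antagonists and Wnt pathway genes were compared next. Sfrp1 read 238 in the heterozygote and 5029 in the knockout, and its 5 probe sets ranged from 14.2-fold to 44.9-fold higher. Sfrp2, with 1 probe set, read 334 and 7740.0. Dkk2 was 2.71-fold higher (log2 ratio 0.86 with a pseudocount of 50), whereas Dkk3 was 3.09-fold lower (2098 against 679) and 2.26-fold lower by its other probe set. Of 10 measured antagonists 3 were at least 2-fold higher and 1 lower (median log2 ratio 0.45, percentile 97.9, and 97.4 after quantile normalization). That median ranged from 0.19 with a pseudocount of 50 to 0.71 with the higher floor. Of 20 measured Wnt ligands and receptors, 8 were at least 2-fold higher and 2 lower (median 0.76, above all 10000 matched lists). These included the receptor Fzd4 (8.47-fold higher), the Wnt agonist Rspo3 (4.42-fold) and the co-receptor Lrp6 (2.91-fold), with Fzd9 2.75-fold lower (log2 ratio -0.72 with a pseudocount of 50). For Lrp6 the mean over probe sets gave a log2 ratio of 0.96, under 2-fold. Of 12 measured target genes of canonical Wnt signalling only Lgr5 passed 2-fold by the probe set used for each gene. With the mean over probe sets Nkd1 did so as well, at a log2 ratio of 1.45. Ccn5 had 889 and 1753, Nkd1 45.4 and 82.5, and Ccnd1, which encodes cyclin D1, 3401 and 1782. The target list had a median log2 ratio of 0.37 (percentile 98.0), 0.20 with spike-in scaling, and its percentile was 97.0 without a floor. Axin2, a widely used reporter of the pathway, singled out after its values were seen, had 40.5 and 29.4.

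Factors by which bone cells are known to support haematopoietic stem cells were mostly higher in the knockout. Of 14 measured genes 7 were at least 2-fold higher and 0 at least 2-fold lower, and their median log2 ratio of 1.01 (0.65 with a pseudocount of 50) lay above all 10000 matched lists. The chemokine Cxcl12, which retains stem cells in the marrow, had the largest ratio, 4.56-fold (1177 against 5367) and 5.26-fold by a second probe set. Another, dim probe set of Cxcl12 read 23.3 in the heterozygote and 3.02 in the knockout, and the mean over all 3 gave a log2 ratio of 0.54. Ptn was 4.06-fold, Igf2 3.18-fold and Tgfb1 2.99-fold higher, the last with a log2 ratio of 0.75 with a pseudocount of 50. Other members, singled out after their values were seen, were under 2-fold: stem cell factor, Kitl, had 115 and 193, angiopoietin 1, Angpt1, 51.5 and 96.3, and the adhesion molecule Vcam1 631 and 715. On the same array, leukocyte and macrophage genes were lower (median log2 ratio -1.99).

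**Figure D2:**
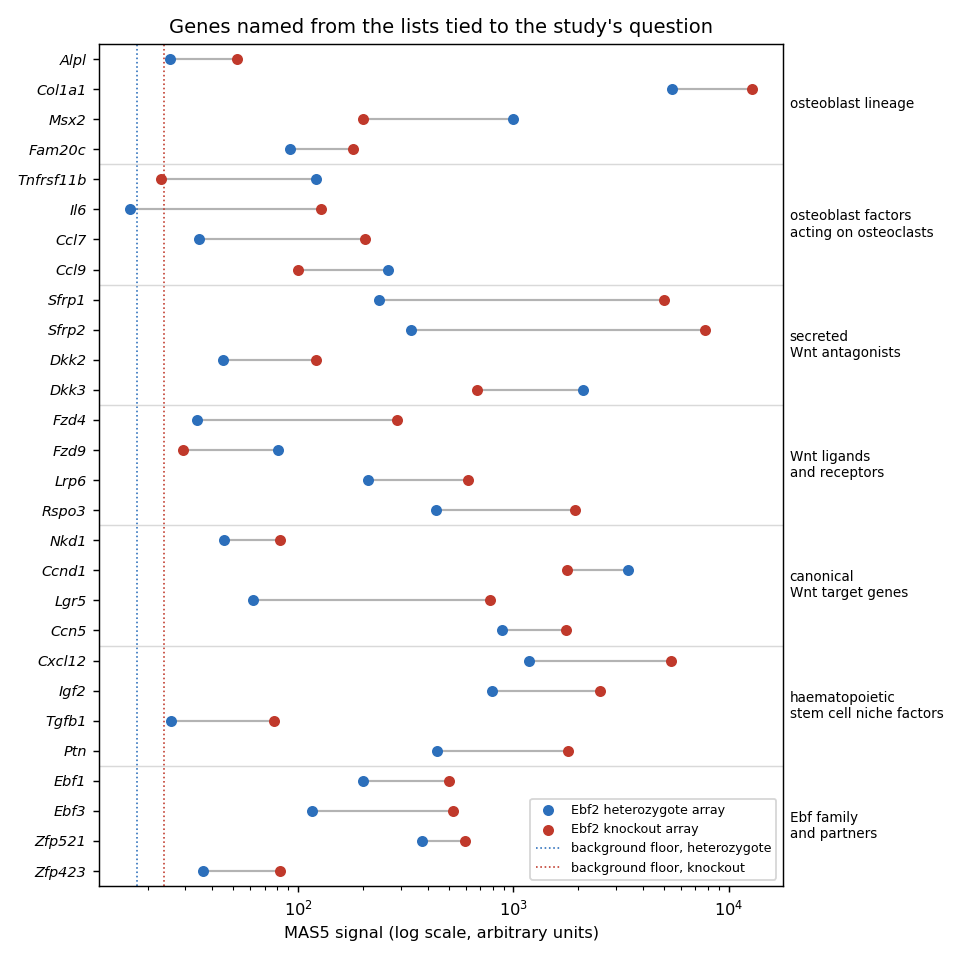
MAS5 signal (log scale, arbitrary units) on the heterozygote (blue) and knockout (red) array of the genes named from the 7 lists tied to the study's question; dotted lines are the background floors of the arrays, and each point is 1 array. Sfrp1, Sfrp2, Lgr5 and Cxcl12 have their knockout value to the right, and Tnfrsf11b, Msx2 and Dkk3 their heterozygote value.

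Genes of the osteoblast lineage were mostly higher in the knockout, by less than 2-fold. Of 12 measured members 9 had the higher signal in the knockout; 2 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.64 (percentile 99.99). The median was 0.36 with the mean over probe sets, and 0.35 without a floor, where it lay within matched lists (percentile 96.3). Col1a1, the main collagen of bone, had 5478 and 12784 by its brighter probe set (2.33-fold higher), but its second probe set was 1.40-fold lower. Alkaline phosphatase, Alpl, was dim at 25.4 and 51.8, and lay under 2-fold under quantile, lowess and spike-in scaling, without a floor and with a pseudocount of 50. Fam20c, a kinase of secreted proteins, had 91.8 and 179.7. The homeobox gene Msx2 was 4.95-fold lower (992 against 200.5), with a log2 ratio of -1.72 as a mean over probe sets. Sp7, the osteoblast transcription factor osterix, singled out after its values were seen, had 83.7 and 53.3.

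Markers of other cell types differed as well. Macrophage and leukocyte genes were lower in the knockout: 18 of 19 measured members were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.99, below all 10000 matched lists. Fcgr3, an antibody receptor, was 6.48-fold lower and the protease Ctss 6.25-fold lower. The members with the brightest probe sets, named after their values were seen, were the lysozymes Lyz1 (5649.9 against 2001) and Lyz2 (2780.1 against 702), which are close in sequence, so that their signals are not independent, and the receptor Csf1r (1529 against 405). Of the 3 measured osteoclast genes Nfatc1 was 2.37-fold lower, under 2-fold as a mean over probe sets and with a pseudocount of 50, and Ctsk had 858 and 699.96 (list median -0.29, within matched lists). Of the 16 granulocyte, mast cell and B cell genes with a probe set of their own only Elane was above the floor, at 23.1 in the heterozygote, and 0 of the erythroid genes were measured.

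Chondrocyte genes were split. Of 16 measured members 8 were at least 2-fold lower in the knockout and 2 at least 2-fold higher (median log2 ratio -0.87, below all 10000 matched lists). The median was -1.39 without the 2 members for which no fold is given, and -1.72 over the 13 members above background on both arrays. The main cartilage collagen Col2a1, named after its values were seen, was 3.30-fold lower (8542 against 2592), while the small proteoglycan Epyc was 5.97-fold higher (117 against 699). The cartilage transcription factor Sox9, singled out after its values were seen, had 213 and 209. Of 7 measured Schwann cell and neuron genes 4 were at least 2-fold lower and 1 higher, with a median of -1.20 (-0.71 with a pseudocount of 50); Stmn2 was 3.25-fold and S100b 2.35-fold lower, both under 2-fold with that pseudocount.

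Adipocyte genes were higher: of 8 measured members 6 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 ratio of 1.45, above all 10000 matched lists. The adipogenic transcription factor Cebpa was 8.91-fold higher (39.2 against 349.6; Fabp4 is given above), and the fatty acid transporter Cd36 was at least 4.24-fold lower (log2 ratio -1.16 as a mean over probe sets). Of 11 measured mesenchymal progenitor and fibroblast genes 5 were at least 2-fold higher and 0 lower (median 0.41, percentile 99.2, but 0.23 with spike-in scaling and percentile 96.0 without a floor), among them the receptor Pdgfra (5.45-fold; log2 ratio 1.47 as a mean over probe sets), Thy1 (4.08-fold) and the microfibril protein Mfap5 (3.97-fold). Of 9 tendon genes 3 were at least 2-fold higher (median 0.44, percentile 98.0, but within matched lists at 94.3 after lowess scaling, 94.8 over members above background on both arrays and 95.6 with a pseudocount of 50), with Thbs4 7.12-fold and Chodl at least 6.39-fold. Of 12 pericyte and smooth muscle genes 3 were higher and 1 lower (percentile 89.9), the channel subunits Abcc9 by at least 6.53-fold (log2 ratio 1.69 as a mean over probe sets) and Kcnj8 by at least 3.32-fold, with Mcam at least 2.17-fold lower, but under 2-fold with the higher floor (log2 ratio -0.68) and with a pseudocount of 50 (-0.57). Endothelial genes (4 measured, percentile 84.2) and skeletal muscle genes (6 measured, percentile 47.1, median 0.24 but -0.09 after lowess scaling) lay within matched lists. Ramp2 was 4.27-fold and Acta1 2.32-fold higher, the latter with a log2 ratio of 0.70 with a pseudocount of 50.

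**Figure D3:**
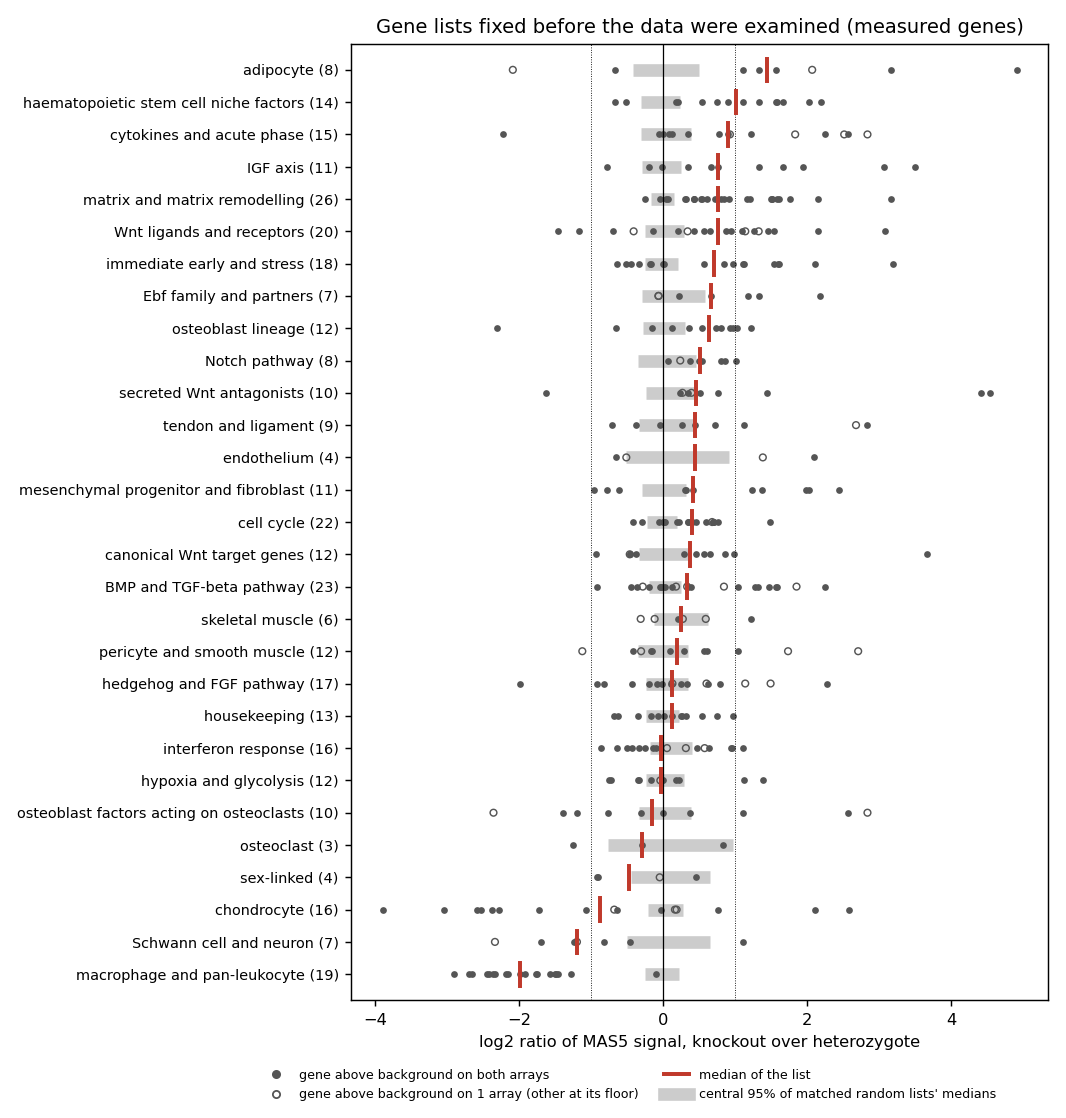
Log2 ratio of MAS5 signal, knockout over heterozygote (x axis), of the measured members of each gene list with at least 3 of them (number in brackets); filled points were above background on both arrays, open points on 1, red bars are list medians and grey bars the central 95% of the medians of matched random lists. The macrophage list lies lowest, with a median of -1.99, and the adipocyte list highest, with 1.45.

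Matrix genes and genes of the insulin-like growth factor axis were higher in the knockout as lists. Of 26 measured matrix genes 10 were at least 2-fold higher and 0 lower (median log2 ratio 0.76, above all 10000 matched lists). Elastin, Eln, was 8.93-fold higher, the proteoglycan decorin, Dcn, 4.43-fold and periostin, Postn, 3.39-fold (2884 against 9763), while fibronectin, Fn1, singled out after its values were seen, had 10368 and 10667. Of 11 genes of the insulin-like growth factor axis 5 were at least 2-fold higher and 0 lower (median 0.77, above all 10000 lists). Igfbp3 was 8.38-fold and Igfbp5 3.85-fold higher, the latter 1.70-fold by its other probe set. Of 23 BMP and TGF-beta genes 8 were at least 2-fold higher and 0 lower (median 0.33, percentile 99.4, but 88.6 after lowess scaling and 86.9 with the array median as floor). That median is the floor-set value of a member for which no fold is given; without the 2 such members it was 0.35 (percentile 99.6). Gdf10 was 4.76-fold and Bmp6 at least 3.61-fold higher, the latter with a log2 ratio of 0.79 with a pseudocount of 50. Of 8 Notch genes 1, Notch3, passed 2-fold at 2.01-fold, and not after quantile or spike-in scaling, without a floor or with a pseudocount of 50 (list median 0.52, percentile 98.8, but 0.34 with spike-in scaling and within matched lists without a floor), and Hes1 had 170 and 306. As a mean over probe sets the log2 ratio of Notch3 was larger, 1.62. Of 17 hedgehog and FGF genes 3 were higher and 1 lower (percentile 72.3), the feedback inhibitor Spry1 by 4.84-fold and the receptor Fgfr3 3.96-fold lower. Their median, 0.13, is also the floor-set value of a gene without a fold; it was 0.18 without that gene, -0.02 over the 13 members above background on both arrays and -0.05 with spike-in scaling.

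Immediate early and stress genes were higher as a list, with 7 of 18 at least 2-fold higher and 0 lower (median log2 ratio 0.71, above all 10000 lists). The AP-1 component Fosb was 9.12-fold, Nr4a1 4.30-fold and Junb 3.05-fold higher. Of 15 cytokine and acute phase genes 6 were at least 2-fold higher and 1 lower (median 0.90, above all 10000 lists, but 0.34 and percentile 92.8 over the 11 members above background on both arrays), among them the neutrophil chemokine Cxcl5, at least 5.71-fold. The 1 lower member was Cxcl2 (136 against 29.3), named for that count. Of 22 cell cycle genes 1, Aurkb, passed 2-fold (2.79-fold higher; log2 ratio 0.86 with a pseudocount of 50), with a list median of 0.39 (percentile 99.97; 0.22 with spike-in scaling), and Ccna2 had 404 and 662. Interferon genes (16 measured, median -0.02, mean 0.11, percentile 16.3) and hypoxia and glycolysis genes (12 measured, median -0.03, mean 0.05, percentile 38.4) lay within matched lists, with Irf1 2.15-fold, Pfkl 2.61-fold and Adm 2.18-fold higher. Irf1 and Adm lay under 2-fold with spike-in scaling, as did Irf1 with a pseudocount of 50.

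Housekeeping genes lay within matched lists (13 measured, 0 past 2-fold, median log2 ratio 0.12, and -0.06 with spike-in scaling). Ywhaz had 1045 and 2049.8, Polr2a 391 and 656, and Hprt 1105 and 687. Female- and male-specific transcripts were present on both arrays: Xist read 255 and 351, and the Y-linked genes Eif2s3y 202 and 107 and Kdm5d 76.0 and 40.7, in the order heterozygote and knockout. The log2 ratio was 0.46 for Xist, -0.91 for Eif2s3y, -0.90 for Kdm5d and -0.05 for the dim Y-linked gene Uty. The mix of sexes may thus differ between the preparations, which was not tested. The sex-linked list pools female- and male-specific transcripts, so its median cannot show such a difference. Its 4 measured genes had a median log2 ratio of -0.47 (percentile 2.03), and 0 passed 2-fold. That list lay within matched lists with the mean over probe sets (percentile 7.57), either other floor, a pseudocount of 50 or no floor (percentile 35.4), and its median ranged from -0.90 to -0.11. Of the 40 named genes nearest to Ebf2, 22 were measured, 3 of them at least 2-fold higher in the knockout and 1 lower, with a median log2 ratio of -0.14 and a mean of 0.11 (percentile 13.4). These 4 genes, named for their count, were Scara5 (3.30-fold higher), Clu (3.11-fold), Stc1 (at least 3.06-fold) and Dock5 (2.22-fold lower).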

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

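The signals here lie in parts of the arrays that the comparison of named genes left out. Of 9160 probe sets without an entry in the gene annotation and not serving as controls, 2095 were above the background floor on at least 1 array, 131 of them at least 2-fold higher and 54 at least 2-fold lower in the knockout. Of 932 probe sets with several gene symbols, 562 were above the floor, 24 of them at least 2-fold higher and 18 lower. Of the 3 control probe sets for 18S ribosomal RNA, the 3' set read 88.9 on the heterozygote and 154 on the knockout array and the middle set 26.7 and 71.0, log2 ratios of 0.79 and 1.41. The 5' set read 16.2, under the floor, and 29.3.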

How the results depend on the processing

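Scaling to the spike-ins, leaving out leukocyte and chondrocyte genes and leaving out genes without a fold were chosen after the data were seen. The counts of genes past 2-fold (742 higher, 408 lower) moved by more than 1.5 times under no floor (2694 and 2308), where dim probe sets enter, and a pseudocount of 50 (280 and 134), which shrinks dim genes; a size of 1.5-fold gave 1871 and 1241, and 3-fold gave 252 and 120. Spike-in scaling gave 625 lower genes, by construction, since it lowers all knockout values. Leaving out leukocyte and chondrocyte list genes gave 740 and 366. The genes left out went beyond the fixed macrophage and chondrocyte lists, which hold 18 and 8 of the 408 lower genes. Without the 609 genes that have no fold, all 20 lists outside the matched range stayed outside, and the chondrocyte median was -1.39 in place of -0.87. The median of the secreted Wnt antagonists was 0.19 in place of 0.45 with the pseudocount of 50. None of the named genes past 2-fold and none of the list medians outside matched lists changed sign under any alternative run. Of the 20 lists outside the matched range, 14 to 20 stayed outside on the same side; the BMP and TGF-beta (lowess, median floor, pseudocount), tendon (lowess, pseudocount, both-array genes), secreted Wnt antagonist (quantile, no floor, pseudocount) and sex-linked lists left it most often. Without a floor the osteoblast (percentile 96.3), canonical Wnt target, Notch and fibroblast lists left it, as did the cytokine list (percentile 92.8) over genes above the floor on both arrays. The 30 extreme genes were all past 2-fold the same way in each alternative, among those it measured: leaving out probe sets ending in _s_at or _x_at measured 27 of them, since Wfdc18, Dlk1 and Hpgd have no value there, and genes above the floor on both arrays are 20 of them by construction. The size of their ratios was less stable. With the pseudocount of 50 the log2 ratio went from 4.91 to 3.14 for Fabp4, from 3.60 to 1.99 for Shox2 and from -2.35 to -1.23 for Tnfrsf11b. Of 88 named genes past 2-fold, 5 fell short with the mean over probe sets (Adm, Col1a1, Cxcl12, Lrp6 and Nfatc1), 16 with the pseudocount of 50 (Acta1, Alpl, Aurkb, Bmp6, Dkk2, Fzd9, Irf1, Mcam, Nfatc1, Notch3, S100b, Spry4, Stmn2, Tek, Tgfb1 and Zfp423) and 5 with spike-in scaling (Adm, Alpl, Egr1, Irf1 and Notch3). The cause of these shifts was not tested. Ebf2 stayed between -0.46 and 0.38 on the log2 scale, and the median of the genes next to it between -0.31 and -0.02. Of lists within the matched range, those whose median changed sign with the scaling were the skeletal muscle (-0.09, lowess), hedgehog and FGF (-0.05, spike-in) and housekeeping (-0.06, spike-in) lists, and without a floor the endothelial (-0.18) and osteoclast (0.09) lists did so, as did the interferon list (0.02) with the mean over probe sets, the hedgehog and FGF list (-0.02) over genes above the floor on both arrays and the skeletal muscle list with the pseudocount of 50. Signal over background limits the dim genes: 1238 genes were above the floor in the heterozygote only and 490 in the knockout only. No paired analysis was possible because each genotype has 1 array. Leaving out a replicate was not possible for the same reason.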

Other observations

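All gene groups in the first 2 paragraphs were added after the results of the fixed lists had been seen; the elastic fibre, complement and antioxidant lists were drawn up after their leading genes had been seen, the unfolded protein response and axon guidance lists after some of their members (Pdia4, Sema4f and Sema3a) had been seen, and the others before any value of their members was examined. Of 18 measured elastic fibre and microfibril genes 8 were at least 2-fold higher in the knockout and 1 lower, with a median log2 ratio of 0.86. The microfibril gene Mfap4 was 7.85-fold and Fbn2 6.66-fold higher. Of 30 antioxidant and detoxifying genes 9 were at least 2-fold higher and 2 lower (median 0.24), the extracellular glutathione peroxidase Gpx3 9.12-fold and cytoglobin, Cygb, 7.02-fold. Of 12 complement genes 4 were higher and 2 lower (median 0.91): the C1 inhibitor gene Serping1 was 7.87-fold higher, Masp1 3.45-fold lower and Cfp, properdin, at least 3.62-fold lower.

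Of 11 limb identity factors 2, Shox2 and En1 (at least 2.65-fold), were at least 2-fold higher and 0 lower (median 0.53, percentile 99.4 of matched lists, but 88.4 over the 7 above background on both arrays), and of the 3 measured posterior Hox genes Hoxd8 was 2.30-fold higher (percentile 90.4). Of 38 axon guidance genes 10 were higher and 2 lower (percentile 99.8); the ephrin receptor Ephb4 was 5.89-fold higher, and the semaphorins Sema4f and Sema3e were 4.57-fold and 3.98-fold lower. Of 20 unfolded protein response genes 3 were at least 2-fold higher and 0 lower (median 0.26, percentile 99.3), among them Pdia4 (8.72-fold) and calreticulin, Calr (2.08-fold). The 25 ribosomal protein genes (median 0.05), 33 oxidative phosphorylation genes (median -0.16, percentile 3.43) and 15 cholesterol synthesis genes (median 0.09) lay within matched lists, and of these 3 lists only Dhcr7 passed 2-fold (2.39-fold higher).

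The tests in the 3 paragraphs that follow were all chosen after the results were seen. Macrophage genes were 3.96-fold lower in the knockout at the median of 19 genes, none of which another fixed list holds (overlap 0). Array scaling is argued against as the cause, since the spike-ins had a mean log2 ratio of 0.18, and 2 SD below it was -0.11, far above the macrophage median of -1.99. A second list of 49 macrophage and blood cell genes, sharing 0 genes with the fixed lists, had 36 measured members, 15 at least 2-fold lower and 0 higher, with a median of -0.87 (range of the central 95% of matched lists -0.13 to 0.33; 20 of the 36 were not above background on both arrays), and -0.81 without 2 members, Fermt3 and Cd84, that are also among the extreme genes. Fewer macrophages in the knockout preparation would give such values. Macrophage genes such as Csf1r (1529 in the heterozygote, 405 in the knockout) were above background on both arrays after the sort for lacZ. How the sort treats macrophages was not tested. With 1 array per genotype, an effect of the genotype on macrophages cannot be told apart from a difference between the preparations. The marker used for the sort lies in the Ebf2 locus, so the sort may itself have differed by genotype. More arrays alone would not settle that, and it limits the patterns below as well.

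Sfrp1 and Sfrp2 were 21.2-fold and 23.1-fold higher in the knockout. Losing macrophages and chondrocytes may enrich all remaining RNA. The matrix list had a median log2 ratio of 0.76, and its median plus 2 SD was 2.31, under the 4.40 and 4.53 of the pair. The pair is among the 10 highest ratios, and the SD is a spread between genes, so this comparison could hardly come out otherwise. It does not decide how far such enrichment contributed. More 3' biased RNA in the knockout, of the size seen in the controls, is argued against for Sfrp1 only. The lowest of its 5 probe sets gave a log2 ratio of 3.83, while the beta-actin 3' over 5' ratio shifted by 0.50. Where these probe sets lie along the transcript is not known here. Sfrp2 has 1 probe set, so the comparison does not cover it. A different mix of mesenchymal cells stays open, as the adipocyte list (median 1.45), the fibroblast list and the chondrocyte list differed as such a mix, or the genotype acting within the cells, would make them differ. These cannot be told apart with 1 array per genotype.

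Chondrocyte genes had a median log2 ratio of -0.87 in the knockout, and -1.72 over the 13 members above background on both arrays. A smaller share of chondrocytes as the whole cause would lower markers that only chondrocytes make. Of 10 members at least 2-fold above the floor on both arrays 1, Epyc, was higher by more than 2-fold plus the probe set SD (5.97-fold). Comp had 232 and 395, and Sox9 213 and 209, in the order heterozygote and knockout. Prg4, near the floor in the heterozygote only, was 4.30-fold higher. The mark set against a smaller share as the whole cause was 2 or more members like Epyc, and 1 was found, so the test does not decide. Other cells might also make these transcripts. With 1 array per genotype, a smaller share of chondrocytes cannot be told apart from a change within the cells.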
